A study of Homo sapiens with 8 samples.

How the data were processed

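RNA of A2780 and of 4 derivatives was compared on 8 spotted cDNA arrays of 2 channels, 2 arrays for each of CPR20, CPR40, CPR55 and CPR70. Per the labels, the derivative carried Cy5 and the parent Cy3 on every array, so no array has the dyes exchanged. The deposited channel file gives, per the file headers, an intensity for the red and the green channel of each spot, a calibrated ratio and a spot area. The calibrated ratio equals red over green intensity times 1 factor per array, read from the values. The deposited value table holds the log2 of that calibrated ratio, derivative over parent, and is not centred. The intensity columns have no background beside them, and the method by which the authors obtained them is not given in the sources used here, nor are the scanner, the image software and the print-tip layout. Of the 40 value columns 8, from 2 arrays, matched no sample and were not used here.

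The channel file holds 15360 spots: 14182 of 13141 annotated clones, 741 that are empty or without data, and 437 without annotation. Gene names in the file were brought to current symbols where a table gave a single match: 6338 clones had a current name, 2467 an older one, 2251 an unmatched name and 288 an ambiguous name, both kept as in the file, and 1797 none. Spots of area 0, which carry the value 1 in both channels, were set to missing; they made up 0.67% to 15.1% of spots per array. Log2 ratios of the channel intensities, with a floor of 1, were normalised by loess within each array (span 0.3, 4 iterations), and spots of a clone were averaged. Only the 10646 clones measured on all 8 arrays were tested; 2495 were left out. The planned normexp correction needs a background column and was replaced by the intensities as deposited.

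Comparisons were made with limma 3.58.1 in R 4.3.3, with 1 mean per derivative, empirical Bayes variances (4 residual degrees of freedom, prior 3.34) and Benjamini-Hochberg adjustment over the clones of each comparison at 0.05. Each derivative and the mean of the 4 were tested against 0, and a linear trend on the number in the name, CPR70 minus CPR20 and a moderated F test compared the derivatives. The replicate number was not a block in the design. A check of the deviations of arrays from their derivative's mean gave correlations of 0.237 to 0.324 between same-numbered arrays in all 6 pairs of derivatives. Same-numbered arrays thus share a deviation and are called a slide series here. What they share is not given in the sources used here. Results with the number as a block stand beside the others. Gene lists, 27 with at least 5 measured genes, were tested with camera at a preset correlation of 0.01 and again with an estimated one. With an estimated one camera also tests on the residual degrees of freedom of the arrays. A list can then lose its call without correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.

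A gene was represented by its brightest clone. Named genes are the 12 largest rises and 12 largest falls of the mean among genes past the threshold with 1 sign on all 8 arrays, the 6 and 6 of each derivative with 1 sign on both arrays, up to 4 genes past the threshold of each list, and 10 genes of platinum handling whatever their test. For the trend and for CPR70 against CPR20, where none passed, the 5 smallest p in each direction are named. The lists, the rule for named genes and the tests of the comparisons were fixed before the data were examined; some tests of explanations in the closing section were not. BST2, IFI16 and MDM2 were added afterwards. Some genes that this rule names are not reported here. The handling of spots of area 0, the limit to clones measured on all arrays and the blank level were set after the files were seen. A channel was taken as not well above background where it stayed at or below the 95th percentile of blank spots of the array on all arrays of the comparison. The change is then given as a lower bound in fold, with the dim channel raised to the lowest level seen above the blank one, and as a direction alone where that bound is under 1 or both channels are dim.

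The method was tested on simulated data with 200 changed clones of 10646. Of 4-fold changes it recovered 96% in the mean, 66.5% in CPR70 against the parent, 22% in CPR70 against CPR20 and 32% in the trend. With the replicate number as a block it recovered 47% in CPR70 against CPR20 and 52.5% in the trend. The simulated slide series gave 321 to 425 false calls in the mean and 1183 to 1293 with the replicate block. They gave 60 to 107 with the series as a random effect and 169 to 192 for calls in each series alone. The counts of the mean can thus hold more false calls than the threshold implies. The simulated series effect included array noise and was stronger than in the data. Unchanged derivatives correlated at 0.384 to 0.396 in it, against 0.237 to 0.324 for the deviations of same-numbered arrays. False calls may therefore be fewer than simulated, and recovery without the block higher. The median 95% interval reached 0.71 on the log2 scale to either side for a derivative and 0.35 for the mean. Alternatives covered the normalization, the starting values, dim clones, the replicate block, the variance model, clones of a gene, single arrays and the size of change; 8 more were added after the data were seen, for the intensity offset, missing spots, the slide series, dim channels and the floor.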

Results

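A2780 is an established human ovarian carcinoma cell line that is killed by cisplatin, a platinum drug that crosslinks DNA. The study compared 4 cisplatin-resistant derivatives of this line, named CPR20, CPR40, CPR55 and CPR70, with the sensitive parent on 2-colour spotted cDNA arrays, and asked how gene expression differs in cells of increasing resistance. What the number in each name measures is not given in the sources used here. Each derivative was hybridised on 2 arrays, and on all 8 arrays the derivative was labelled with Cy5 and the parent with Cy3. A positive log2 ratio therefore means more transcript in the derivative. The arrays carried 13141 annotated clones, of which 10646 were measured on all 8 arrays; 9197 of these had a gene name, for 8299 genes. Signal was modest on several arrays. Between 13.9% and 53.4% of gene spots exceeded the level of blank spots in the derivative channel, and between 8.9% and 39.8% did so in the parent channel. The labels do not say whether the 2 hybridisations of a derivative came from separate cultures, so p-values measure only the spread between hybridisations.

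The mean of the 4 derivatives was compared with the parent; a gene past the threshold there need not have changed in each derivative. The largest rise was that of CAVIN2, a coat protein of caveolae, at least 21.6-fold higher in the derivatives (adjusted p = 1.4e-05), with parent signal not well above background on any array. Among the largest falls, HAPLN1, which links hyaluronan to proteoglycans, fell by 4.93 ± 0.43 on the log2 scale (SD, n = 8 arrays; adjusted p = 1e-05; derivative signal above the blank level on 3 arrays), and PCOLCE, an enhancer of procollagen processing, fell by 4.53 ± 0.64 (adjusted p = 1e-05). CDKN1A, the p21 inhibitor of cell division, was at least 2.94-fold lower (adjusted p = 0.00046), with derivative signal not well above background on any array.

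Among the other large rises, MGC3032, an uncharacterised gene under its file name, rose by 3.87 ± 0.35 (parent signal above the blank level on 3 of 8 arrays). ATP11B, a phospholipid-transporting ATPase, rose by 3.66 ± 1.07 at its brightest clone and by 2.93 at its second clone. NRG1, a growth factor of the EGF family, rose by 2.97 ± 1.21. Parent signal of both was above the blank level on 2 of 8 arrays. MID1, a ubiquitin ligase bound to microtubules, rose by 3.78 ± 2.48 and the metalloproteinase MMP3 by 3.50 ± 2.18. Both varied widely, and their parent signal was above the blank level on 2 arrays and 1 array. For the remaining named rises the parent signal was not well above background on any array. The homeodomain factor ISL1 was at least 4.28-fold higher, the metalloproteinase inhibitor TIMP1 at least 2.49-fold, the secreted glycoprotein LGALS3BP at least 2.00-fold, the tight junction protein CLDN16 at least 1.55-fold and the glutathione transferase MGST1 at least 1.20-fold (adjusted p from 0.0014 to 0.0059). The second TIMP1 clone read -0.08 (adjusted p = 0.69), so its clones disagree.

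Among the other large falls, the calcium-binding protein S100A11 fell by 3.91 ± 0.51 (derivative signal above the blank level on 1 of 8 arrays) and FLJ20128 by 3.34 ± 0.30. COL3A1, a fibrillar collagen, fell by 2.66 ± 1.38, and PHLDA3, a p53-induced inhibitor of AKT, by 2.63 ± 0.77 (derivative signal above the blank level on 1 of 8 arrays). The second HAPLN1 clone fell by 2.44. Derivative signal was not well above background on any array for TCIM, at least 2.92-fold lower, MGC3047, at least 2.91-fold lower, KIAA0512, at least 3.40-fold lower, and 2 transcription factors, SNAI2 and TCF4, at least 2.78-fold and 2.50-fold lower (adjusted p from 5e-04 to 0.013).

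**Figure D1:**
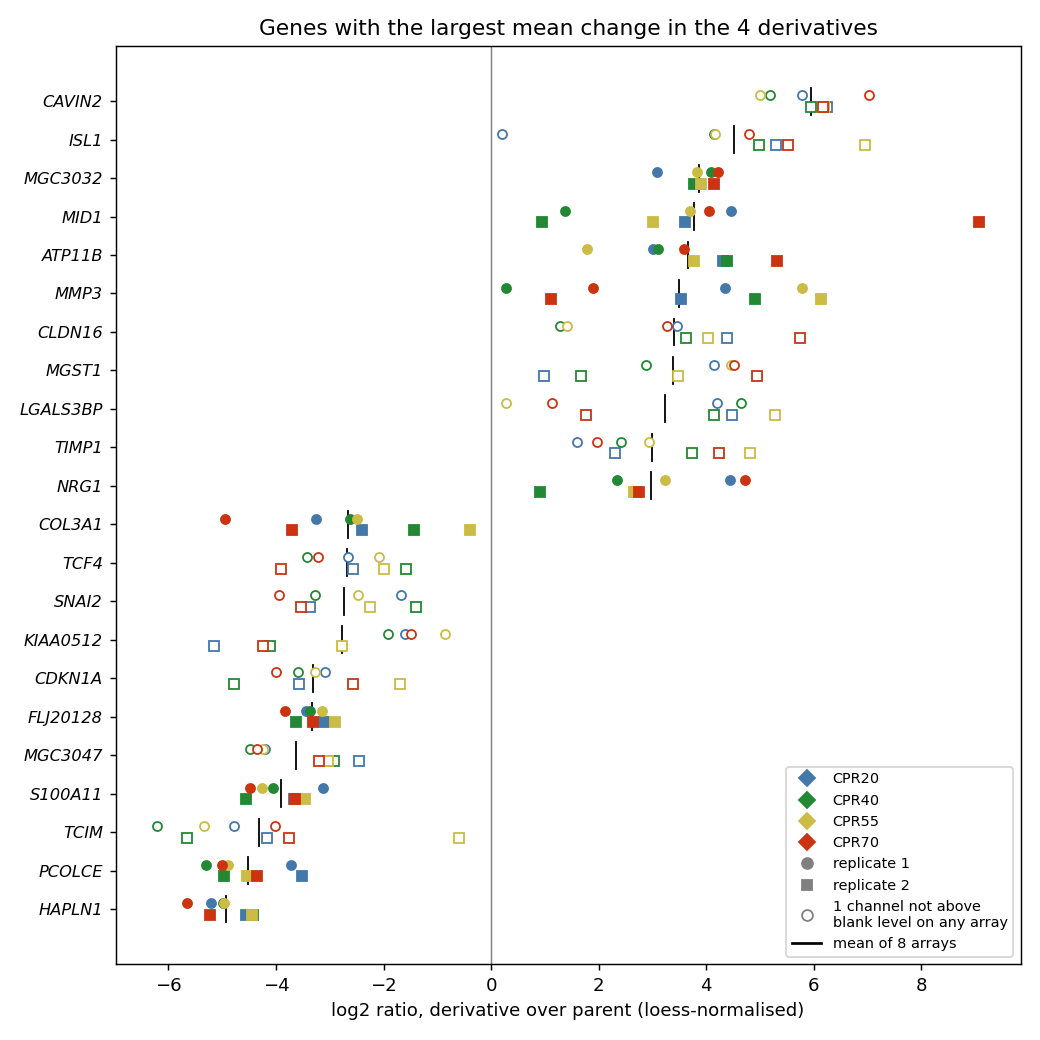
Log2 ratio of derivative over parent on each of the 8 arrays (horizontal axis) for the 11 genes with the largest rise and the 11 with the largest fall in the mean of the 4 derivatives; colours give the derivative, circles and squares replicates 1 and 2, bars the mean, and open symbols genes with 1 channel not above the blank level on any array. All 8 arrays lie on the same side of 0 for each gene, which was a condition for naming it.

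In this comparison 1514 of 10646 clones passed an adjusted p of 0.05: 891 rose and 623 fell, and 1209 of them (79.9%) had the same sign on all 8 arrays. With the replicate number as a block, 2545 clones passed (1421 higher, 1124 lower). On simulated data the block gave 1183 to 1293 false calls, against 321 to 425 without it. The arrays of replicate 1 alone called 1024 clones and those of replicate 2 alone called 2091; 487 were called in both with the same direction (297 higher, 190 lower) and 14 with opposite directions, and on simulated data this rule gave 169 to 192 false calls. With the slide series as a random effect 561 clones passed, all within the 1514, and with median centring in place of loess 397 passed. The count fell to 802 and 656 without CPR20 replicate 1 or 2, and to 996 and 844 without CPR70 replicate 1 or 2. The parent served as 1 control sample in 1 dye, so its own spread is left out and a dye effect of a clone cannot be separated from a change.

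Interferon-stimulated genes encode antiviral and antigen-presenting proteins. Of 33 measured interferon-stimulated genes, 14 rose, 2 fell and 17 did not pass (16 and 4 adjusted over the list alone; 8 and 1 with the slide series as a random effect). The ubiquitin-like ISG15 rose by 2.43 ± 1.11, the antiviral membrane protein IFITM2 by 2.04 ± 0.89, HLA-F by 1.93 ± 1.14 and the class I light chain B2M by 1.45 ± 0.55 (SD, n = 8 arrays). HLA genes are similar in sequence and may share a probe's signal. The 2 that fell, named after their values were seen, were BST2 and IFI16. As a group the list was shifted upwards (camera adjusted p = 0.001), with a median log2 ratio of 0.92 on the replicate 1 arrays and 0.35 on the replicate 2 arrays (adjusted p = 0.0012 and 0.017). With an estimated correlation between genes the list did not pass (adjusted p = 0.33). That correlation was -0.01, below the preset 0.01, so a higher correlation is not what removed the call.

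Genes of the unfolded protein and amino acid response adapt cells to misfolded proteins and to lack of amino acids. Of 19 measured, 10 fell, none rose and 9 did not pass (10 fell adjusted over the list alone, 5 with the random effect). The amino acid transporter subunits SLC7A5 and SLC3A2 fell by 1.47 ± 0.52 and 1.00 ± 0.60, asparagine synthetase ASNS by 1.35 ± 1.04 and SESN2, a stress-induced regulator of mTORC1, by 1.30 ± 0.42 (derivative signal above the blank level on 1 of 8 arrays); the second SLC7A5 clone fell by 1.43. The list's median was -0.55 on the replicate 1 arrays and -0.50 on the replicate 2 arrays (camera adjusted p = 0.00025 over all arrays, 0.00047 and 0.014 within each; adjusted p = 0.43 with an estimated correlation). Of 15 cytosolic heat shock proteins 8 rose, none fell and 7 did not pass (10 rose adjusted over the list alone, 2 with the random effect). HSPA1L rose by 1.10 ± 0.50, HSPA8 by 0.78 ± 0.39 (parent signal above the blank level on 1 of 8 arrays) and the co-chaperone BAG3 by 0.76 ± 0.34 (0.47 at its second clone, adjusted p = 0.095), and the small heat shock protein CRYAB was at least 1.16-fold higher in the mean, on 7 of 8 arrays, but did not pass in CPR70 (adjusted p = 0.96). This list's medians were 0.60 and 0.50 on the replicate 1 and replicate 2 arrays (camera adjusted p = 0.00036 over all arrays, 0.02 and 0.0037 within each; adjusted p = 0.43 with an estimated correlation).

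Most ribosomal protein genes did not pass. Of 61 measured, 8 fell, 2 rose and 51 did neither (13 fell and 2 rose adjusted over the list alone; 1 fell and 0 rose with the random effect). RPS12 fell by 1.04 ± 0.64 and RPS23 by 0.78 ± 0.28, while RPL26 rose by 0.77 ± 0.38 and RPS25 by 0.63 ± 0.25; the second RPL26 clone fell by 0.52 (adjusted p = 0.024), opposite to the first. The shift of the list (camera adjusted p = 0.00025; 0.43 with an estimated correlation) was not past the threshold with median centring (adjusted p = 0.12) or on the replicate 1 arrays alone (adjusted p = 0.067). These 4 lists were the ones past the threshold among 27 tested. With an estimated correlation, and the fewer degrees of freedom of that test, 0 of 27 passed.

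p53 target genes moved in both directions. Of 19 measured, 5 fell and 2 rose (7 and 3 adjusted over the list alone). As a group the list leaned downwards without passing (camera adjusted p = 0.095, 0.098 with the replicate block and 0.43 with an estimated correlation). It passed downwards under several alternatives, among them median centring (0.0095), the series matrix log ratios (0.011) and the dimmest 50% left out (0.0018). On the replicate 1 arrays alone it passed (0.02), and on the replicate 2 arrays alone it did not (0.39). CDKN1A, PHLDA3 and SESN2 were among the falls. IGFBP3, which binds insulin-like growth factors, was at least 1.07-fold higher, and PMAIP1, a BH3-only death protein, was higher on all 8 arrays (adjusted p = 0.0062) with parent signal not well above background. MDM2, the p53 ubiquitin ligase, named here after its values were seen, read 0.06 ± 0.80 (adjusted p = 0.91). Of 13 anti-apoptotic genes 2 fell and 1 rose (3 and 1 adjusted over the list alone): BCL2L2 fell by 0.74 ± 0.25, BAG3 rose and BAG1 was lower on 7 of 8 arrays, with derivative signal above the blank level on 1 array and parent signal on 2, so its size is not given. Of 17 pro-apoptotic genes 2 rose, PMAIP1 and CASP9, and none fell (4 and 0 adjusted over the list alone). Of 42 proliferation genes 2 rose and 3 fell (2 and 2 adjusted over the list alone), among them securin PTTG1, up by 0.97 ± 0.43, BUB3, up by 0.50 ± 0.20, and the mitotic protein CENPF, which fell by 0.82 ± 0.20.

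Genes that handle platinum and its conjugates were examined by name. Some passed in the mean, as did 1514 of all 10646 clones. None of the lists in this paragraph was shifted as a group. Camera adjusted p was 0.9 for copper and platinum transport, 0.75 for ABC transporters and 0.85 for glutathione genes. It was 0.11 for metallothioneins and 0.9 for NRF2 targets. SLC31A1, the copper importer that also admits cisplatin, fell by 0.88 ± 0.32 (adjusted p = 0.0095). The copper exporters did not pass: ATP7A read 0.11 ± 0.69 and ATP7B -0.10 ± 0.33 (adjusted p = 0.74 and 0.69), and neither channel was above the blank level on more than 2 of 8 arrays. Of 10 copper and platinum transport genes 1 rose, SCO1, and 1 fell (2 and 2 adjusted over the list alone). Of 17 ABC transporters 3 rose and none fell (3 and 0 adjusted over the list alone): the lipid transporter ABCA3 was at least 3.19-fold higher (adjusted p = 0.00015), the efflux pump ABCB1 rose by 1.37 ± 0.99 (adjusted p = 0.015; parent signal above the blank level on 1 of 8 arrays) and ABCC1 rose by 0.78 ± 0.24 (adjusted p = 0.007). ABCC2 was not well above background in either channel (adjusted p = 0.58). Of 21 glutathione genes 4 rose and none fell (4 and 0 adjusted over the list alone): MGST1, glutaredoxin GLRX by 1.29 ± 0.63, GSTO1 by 0.77 ± 0.23 and GSTP1 by 0.62 ± 0.24 (adjusted p = 0.016). GCLC, the catalytic subunit of glutathione synthesis, did not pass (adjusted p = 0.88; parent signal not well above background). MT2A was the 1 metallothionein of 5 past the threshold (adjusted p = 0.04; 2 of 5 adjusted over the list alone), higher on 7 of 8 arrays but above the blank level on 1 derivative array and on none in the parent channel. Of 20 NRF2 target genes 2 rose and 2 fell (2 and 2 adjusted over the list alone): EPHX1 and PGD rose by 1.10 ± 0.51 and 0.68 ± 0.32, and FTH1 and AKR1C3 fell by 0.76 ± 0.41 and 0.68 ± 0.38, AKR1C3 with each channel above the blank level on 2 of 8 arrays. With the slide series as a random effect SLC31A1, ABCB1, GSTP1 and MT2A did not pass (adjusted p = 0.062, 0.1, 0.075 and 0.2), while ABCA3, ABCC1, GLRX, GSTO1 and MGST1 did.

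Some DNA repair genes passed in the mean, as did 1514 of all 10646 clones. Of 20 genes of nucleotide excision repair 2 rose and 2 fell (2 and 2 adjusted over the list alone). TFIIH subunits went both ways: GTF2H4 and ERCC3 rose by 0.76 ± 0.30 and 0.45 ± 0.09, and GTF2H1 fell by 0.75 ± 0.59. DDB2 fell by 0.99 ± 0.63. ERCC1, the nuclease subunit often measured in platinum-treated tumours, read 0.07 ± 0.52 (adjusted p = 0.83). Of 16 mismatch repair genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), among them MSH6, which fell by 0.70 ± 0.28, and RFC3, which rose by 0.46 ± 0.33. None of 15 genes of homologous recombination and the Fanconi pathway passed, over all clones or adjusted over the list alone.

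Matrix and lineage markers were mixed. Of 23 collagen and matrix genes 4 fell and 2 rose (7 and 4 adjusted over the list alone): COL1A2 fell by 2.60 ± 1.20 (derivative signal above the blank level on 1 of 8 arrays, parent signal on 4) and the proteoglycan LUM was at least 2.43-fold lower, whereas COL5A2 rose by 1.36 ± 0.65. Of 10 fibroblast markers 4 fell and none rose (5 and 2 adjusted over the list alone); 3 of these, COL3A1, COL1A2 and LUM, are also in the collagen list, and the fourth, PDGFRB, was at least 1.10-fold lower. Of 17 mesenchymal markers 3 rose and 2 fell (5 and 2 adjusted over the list alone): ACTA2, smooth muscle actin, rose by 2.49 ± 1.44, and the transcription factors SNAI2 and TWIST1 fell, TWIST1 by 2.41 ± 0.64 (derivative signal above the blank level on 2 of 8 arrays). CDH2, N-cadherin, passed with a higher mean (adjusted p = 0.049), on 6 of 8 arrays. Of 17 epithelial markers 3 rose and none fell (4 and 1 adjusted over the list alone): CD24 by 0.68 ± 0.35, EPCAM, higher on 6 of 8 arrays and above the blank level on 2 derivative arrays, and ELF3, not well above background in either channel. Of 11 stem-like and drug tolerance markers 2 rose (4 higher and 1 lower adjusted over the list alone), CD24 and the aldehyde dehydrogenase ALDH1A1, the latter by 1.81 ± 1.43. Parent signal of both was above the blank level on 1 of 8 arrays. Leukocyte markers had 1 fall, CD48, among 22 (1 adjusted over the list alone), and none of 6 endothelial and blood markers passed by either adjustment.

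Among metabolic and signalling lists, 5 of 21 cholesterol synthesis genes rose and none fell (6 and 0 adjusted over the list alone), including TM7SF2, a sterol reductase, up by 1.26 ± 0.83. Of 22 glycolysis and hypoxia genes 3 rose and 2 fell (3 and 2 adjusted over the list alone): ENO2 was at least 1.41-fold higher, GPI and HK2 rose by 0.69 ± 0.38 and 0.61 ± 0.12, and ENO1 fell by 0.57 ± 0.30. This list's median was -0.30 on the replicate 1 arrays and 0.44 on the replicate 2 arrays, so the 2 slide series differ in sign. Both shifts passed (camera adjusted p = 0.02 and 0.017) with the preset correlation of 0.01 between genes. The estimated correlation of this list was 0.359, the highest of all lists, and was not applied to the single series. In the mean, where the opposite shifts cancel, the list did not pass with either correlation. Of 21 cytokine and NF-kB target genes 3 rose and none fell (3 and 0 adjusted over the list alone): LIF by 2.33 ± 0.86, TNF by 0.61 ± 0.59 and PLAUR by 0.49 ± 0.44. Parent signal of each was above the blank level on 1 of 8 arrays. The second clones of TNF and PLAUR read 0.14 and -0.52 (adjusted p = 0.51 and 0.074). Of 68 respiratory chain genes 7 rose and 4 fell (7 and 4 adjusted over the list alone), with COX7A2 up by 0.93 ± 0.35 and COX7A2L down, at -1.01 ± 0.48. The mesenchymal, glycolysis and recombination lists had a median and a mean of opposite sign, so no direction is given for them.

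With the slide series as a random effect fewer genes of most lists passed in the mean. For DNA repair these were 1 higher and 0 lower in nucleotide excision repair, where ERCC3, DDB2 and GTF2H1 did not pass (adjusted p = 0.12, 0.077 and 0.14), and 0 and 1 in mismatch repair, where RFC3 did not (adjusted p = 0.16). Higher and lower genes numbered 3 and 0 for glutathione, 1 and 0 for NRF2 targets, 2 and 0 for ABC transporters, 2 and 4 for p53 targets, 0 and 1 for anti-apoptotic, 1 and 0 for pro-apoptotic and 1 and 1 for proliferation genes. They numbered 1 and 2 for mesenchymal markers, 1 and 3 for collagens and matrix, 0 and 2 for fibroblast markers, 1 and 0 for cytokines, 2 and 0 for glycolysis, 2 and 0 for cholesterol synthesis and 1 and 2 for the respiratory chain. No epithelial, leukocyte, copper transport, metallothionein or stem-like gene passed.

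**Figure D2:**
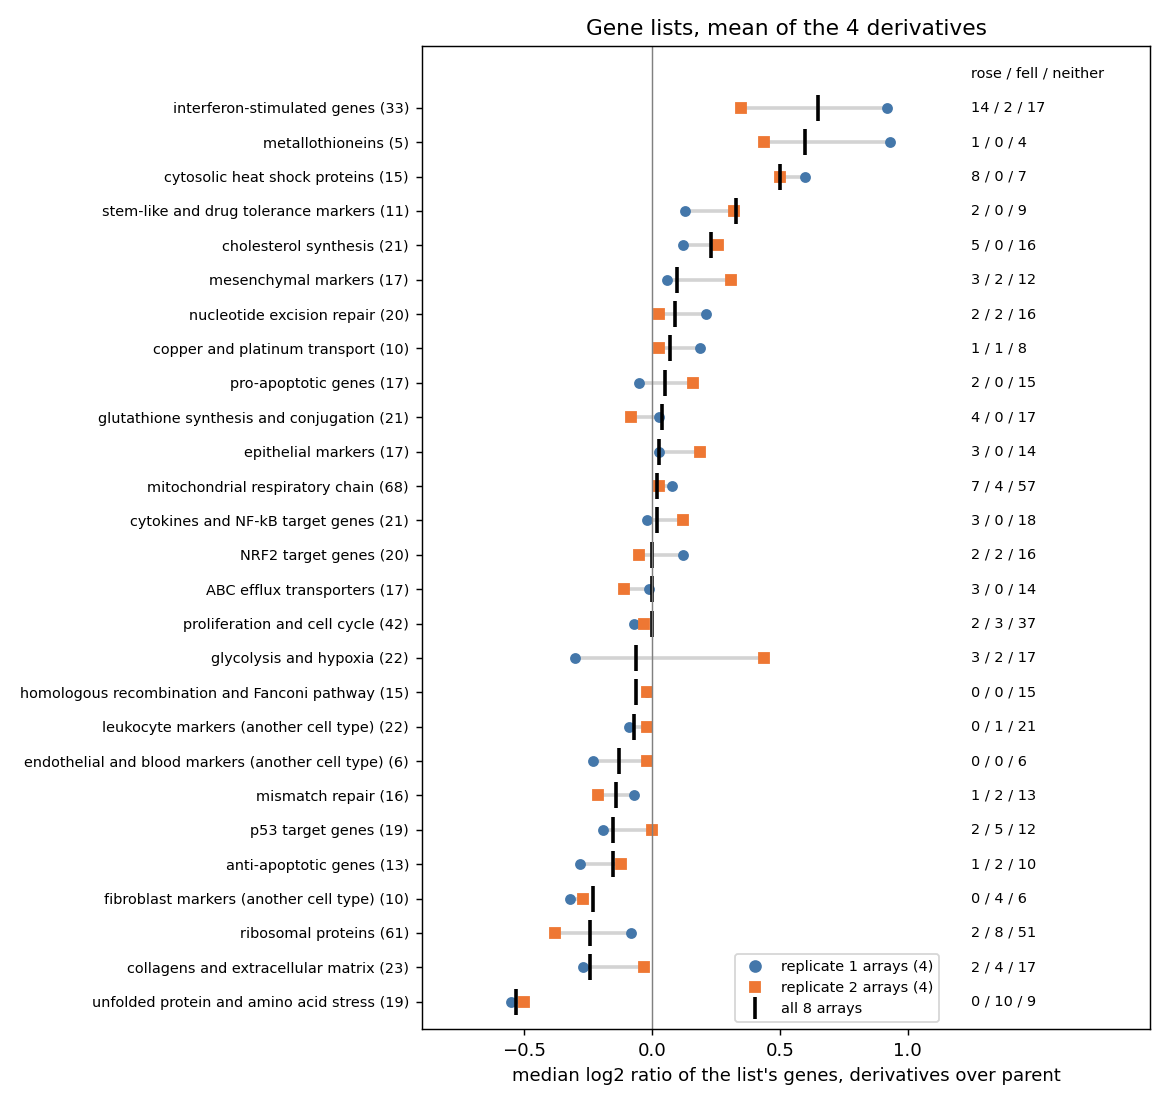
Median log2 ratio of derivatives over parent (horizontal axis) for the genes of each of 27 lists, with the number of genes measured in brackets; circles are the 4 replicate 1 arrays, squares the 4 replicate 2 arrays and bars all 8 arrays, and the numbers at the right count genes that rose, fell or did neither. Interferon-stimulated genes and heat shock proteins lie above 0 and unfolded protein and amino acid genes below 0 on both sets of arrays, while glycolysis and hypoxia genes lie on opposite sides.

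Each derivative was then set against the parent on its own 2 arrays, with the spread estimated over all 8. CAVIN2 was higher in each: at least 24.2-fold in CPR20, 11.6-fold in CPR40, 19.7-fold in CPR55 and 38.9-fold in CPR70. HAPLN1 and PCOLCE were lower in each. HAPLN1 read -4.89 ± 0.45 (SD, n = 2 arrays here and below) in CPR20, -4.71 ± 0.39 in CPR40 and -5.44 ± 0.31 in CPR70, and was at least 10.7-fold lower in CPR55. PCOLCE read -3.62 ± 0.15, -5.13 ± 0.24 and -4.68 ± 0.47 in CPR20, CPR40 and CPR70, and was at least 17.3-fold lower in CPR55. MGC3032 rose by 3.49 ± 0.57 in CPR20, 3.86 ± 0.05 in CPR55 and 4.19 ± 0.05 in CPR70, and was at least 7.04-fold higher in CPR40. S100A11 was at least 5.35-fold lower in CPR20, 7.86-fold in CPR40 and 3.43-fold in CPR55, and fell by 4.06 ± 0.59 in CPR70.

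Other genes were named in some derivatives. In CPR20 the membrane protein TM4SF1 was at least 2.73-fold higher, the axon guidance ligand SLIT2 at least 3.37-fold and the kinase anchor AKAP6 at least 1.97-fold; FLJ20128, PHLDA3 and the chromatin organiser SATB1 fell by 3.27 ± 0.23, 2.39 ± 0.36 and 2.22 ± 0.07. In CPR40 ACTA2 rose by 4.04 ± 1.61, CRYAB was at least 1.75-fold higher, and the secreted proteases MMP10 and ADAMTS5 were at least 1.37-fold and 1.30-fold higher. TCIM was at least 3.80-fold lower there, CDKN1A at least 3.54-fold and the synuclein SNCG at least 2.96-fold. In CPR55 MMP3 was at least 8.83-fold higher, TIMP1 at least 2.91-fold, TM4SF1 at least 2.78-fold and MMP10 at least 1.10-fold; FLJ20128 fell by 3.03 ± 0.17, and TWIST1 and MGC3047 were at least 1.67-fold and 1.53-fold lower. In CPR70 the secreted disulfide isomerase AGR2 was at least 4.77-fold higher and MGST1 at least 3.05-fold, ATP11B rose by 4.45 ± 1.22 and MID1 by 6.57 ± 3.55; COL3A1 and the surface antigen CD99 fell, to -4.32 ± 0.87 and -3.75 ± 0.25, and MGC3047 was at least 7.40-fold lower. Over all 8 arrays the second CD99 clone read -0.41 (adjusted p = 0.17) against -2.45 at the first, so its clones disagree. A gene past the threshold in 1 derivative was not thereby shown to differ from the others.

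The clones past the threshold numbered 42 in CPR20 (29 higher, 13 lower), 84 in CPR40 (41 higher, 43 lower), 160 in CPR70 (88 higher, 72 lower), and in CPR55 69 clones were higher and 35 lower. With the replicate number as a block the counts of CPR20, CPR40, CPR55 and CPR70 were 106, 223, 276 and 391. On simulated data the block also gave more false calls for CPR70 against the parent, 32 to 124 against 0 to 21 without it. With median centring the counts were 2, 11, 4 and 13, and from the deposited log ratios 5, 11, 4 and 11. They depended on single arrays, falling to 0 without CPR20 replicate 2, 22 without CPR40 replicate 2, 8 without CPR55 replicate 1 and 7 without CPR70 replicate 2. Rises in all 4 derivatives numbered 13 clones and falls 9, among them CAVIN2, MGC3032, HAPLN1, PCOLCE and S100A11. Between pairs of derivatives 17 to 34 rises and 9 to 34 falls were shared, where independent lists would share at most 0.57 and simulated unchanged derivatives with the same array series shared 0. Across genes, which are not independent replicates, the changes of 2 derivatives correlated at 0.548 to 0.691, against at most 0.396 in the simulation, and their covariance was 0.189 to 0.244 against at most 0.089. Part of the excess may come from the parent, which is the reference on every array.

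The fixed lists were also tested in each derivative. In CPR70, among p53 target genes 1 rose and 2 fell of 19 (3 and 5 adjusted over the list alone), and 2 of 17 mesenchymal markers fell. In each of the mismatch repair, collagen, leukocyte and fibroblast lists 1 gene fell, and in each of the glutathione, ABC transporter, pro-apoptotic, epithelial, cytokine and glycolysis lists 1 rose; the other lists had 0. No interferon-stimulated gene, heat shock protein or unfolded protein and amino acid gene passed over all clones, whereas adjusted over the list alone 5 rose and 2 fell, 4 rose, and 6 fell. Their medians were 0.51, 0.56 and -0.72, and camera gave adjusted p = 0.054, 0.00078 and 0.00082 (adjusted p = 0.38 for all 3 with an estimated correlation). Ribosomal proteins and p53 target genes were also shifted down and cholesterol synthesis genes up in CPR70 (camera adjusted p = 0.00082, 0.042 and 0.025; 0.59, 0.38 and 0.38 with an estimated correlation). In the other derivatives interferon-stimulated genes were shifted up in CPR20, CPR40 and CPR55 (camera adjusted p = 0.003, 0.029 and 3e-05), unfolded protein and amino acid genes down in CPR40 and CPR55 (5.2e-05 and 0.00033) and heat shock proteins up in CPR40 (2.6e-05). Ribosomal proteins were shifted down in CPR20, CPR40 and CPR55 (0.0045, 0.0061 and 0.0082). Proliferation genes were shifted down in CPR55 (0.0021), p53 target genes down in CPR40 (0.0079), cholesterol synthesis genes up in CPR55 (0.038) and metallothioneins up in CPR40 (0.049). None of these passed with an estimated correlation (adjusted p at least 0.13). With the replicate number as a block metallothioneins in CPR40 did not pass (adjusted p = 0.098), while interferon-stimulated genes and fibroblast markers in CPR70 (0.029 each) and heat shock proteins and fibroblast markers in CPR20 (0.047 each) did, the fibroblast markers downwards. With an estimated correlation these 4 did not pass either (adjusted p = 0.59 in CPR70 and 0.64 in CPR20).

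The 4 derivatives were next compared with one another, to see whether any gene followed the number in the name. None did past the threshold. AGR2 had the smallest p for the trend, while TM4SF1 had the smallest for CPR70 against CPR20. The AGR2 log2 ratios on the 2 CPR70 arrays were 4.57 and 5.91, against -0.15 and 0.88 in CPR20, and its derivative signal was above the blank level on the CPR70 arrays alone. The epithelial adhesion molecule EPCAM read 2.27 and 3.87 in CPR70 against -0.69 and 0.87 in CPR20. TM4SF1 was highest in CPR20 and CPR55, at 4.72 and 3.62 and at 3.77 and 4.74, against 0.56 and 0.36 in CPR70. ANXA1, a phospholipid-binding protein, read 1.32 and 1.72 in CPR20 and -0.96 and -1.30 in CPR70.

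With limma 0 clones passed for the trend over the derivatives, 0 for CPR70 against CPR20 and 0 for any difference among the 4, while 183, 204 and 273 of 10646 clones had an unadjusted p under 0.05. These are 1.72%, 1.92% and 2.56% of clones, below the share of 0.05 that chance alone gives; with the replicate number as a block they numbered 360, 382 and 606. The genes with the smallest p for the trend did not pass (adjusted p = 1 for each): AGR2, RGS20, LOC51334, EPCAM and EML4 leaned upwards with the number, and DKFZP761J17121, TM4SF1, MGC10905, CD48 and ANXA1 downwards. For CPR70 against CPR20 the smallest p belonged to AGR2, RGS20, LOC51334, CFTR and SLAMF8, higher in CPR70, and to TM4SF1, ANXA1, DKFZP761J17121, TP63 and MGC10905, lower (adjusted p = 1). With the replicate number as a block 1 clone passed for CPR70 against CPR20, that of AGR2 (adjusted p = 0.039). No list passed for the trend (0 of 27, also with an estimated correlation), and none of their genes did over all clones; adjusted over the list alone 1 leukocyte marker was lower. The median 95% interval of the CPR70 minus CPR20 difference reached 1.00 on the log2 scale to either side. Of 4-fold differences added to simulated data 22% were recovered, or 47% with the replicate number as a block. Absence of a call is therefore weak evidence here.

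The arrays themselves grouped by replicate number more than by derivative. In the 2662 brightest clones the log2 ratios of different derivatives with the same replicate number correlated at a median of 0.741 (replicate 1) and 0.804 (replicate 2). The 2 arrays of 1 derivative correlated at a median of 0.561, close to the 0.535 of different derivatives with different replicate numbers. These are correlations across clones, which are not independent.

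**Figure D3:**
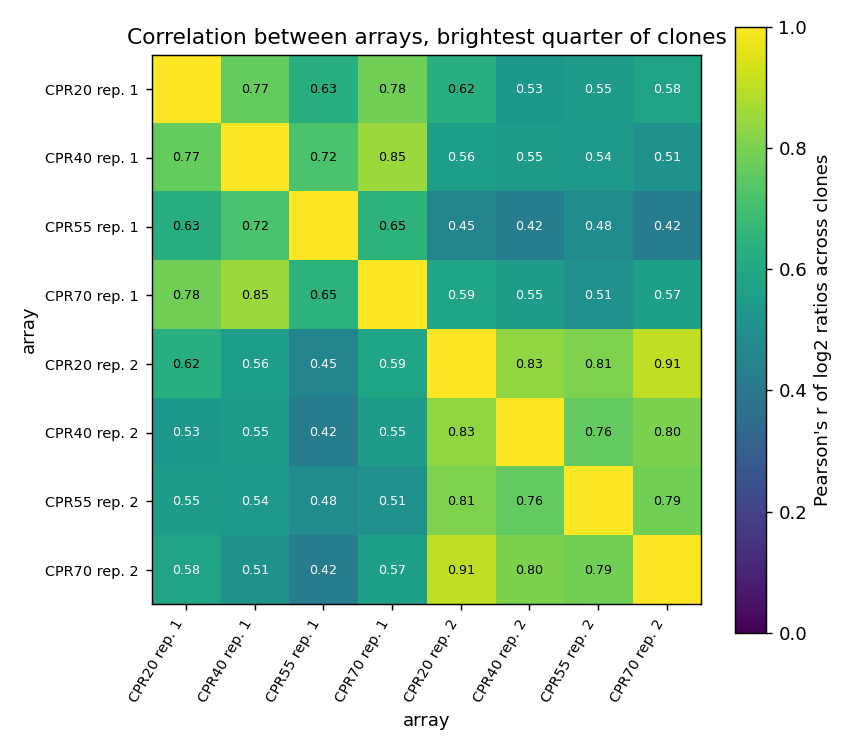
Pearson's r of log2 ratios between each pair of the 8 arrays over the 2662 brightest clones; rows and columns are arrays, ordered by replicate number and then by derivative, and the colour scale runs from 0 to 1. The blocks of arrays with 1 replicate number are brighter than the pairs of 1 derivative.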

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

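The tests of a difference between slide series, of exchanged dyes, of noise of dim spots and of dye bias were chosen after the result was seen. Several named genes were picked out because both arrays of 1 derivative lay above the parent and both arrays of another lay below it. These were LOC51334 (CPR70 above CPR20 by 3.17 on the log2 scale), EML4 (CPR70 above CPR40 by 2.90), ANXA1 (CPR20 above CPR70 by 2.65), TP63 (CPR20 above CPR70 by 2.01), CDH2 (CPR55 above CPR20 by 1.93), SLAMF8 and CFTR (CPR70 above CPR20 by 1.67 and 1.50), ATP7A (CPR20 above CPR40 by 1.22), ABCC2 (CPR40 above CPR70 by 1.10), GCLC (CPR70 above CPR55 by 0.78) and ATP7B (CPR70 above CPR40 by 0.31). The sign rule is not a test of the difference, the pairs were not tested by themselves, and the F test over the 4 derivatives passed for none (adjusted p = 1 for each). LOC51334, CFTR, TP63 and ABCC2 were not well above background in either channel.

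AGR2 was picked out by a test of the difference: CPR70 lay above CPR20 by 4.87, with adjusted p = 0.039 with the replicate number as a block and 1 without it. Clones without annotation enter no comparison of the report. Of 162 tested, 10 passed in the mean of the derivatives, a smaller share than the 1514 of 10646 annotated clones. Of these 10, 6 were higher and 4 lower, with a largest rise of 2.66 and a largest fall of -0.84. Simulated data gave 321 to 425 false calls among 10646 clones in this comparison, so some of the 10 may be false.

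Arrays grouped by slide series more than by derivative. Exchanged dyes in 1 series are argued against by the correlation between the arrays of a derivative, at least 0.271 over all clones. Noise of dim spots is argued against by the brightest clones, where the correlation within a series exceeded that between series by 0.243. A difference between the slide series fits, with deviations of same-numbered arrays correlating at 0.237 or more. The same check defined the series, so it does not tell what the arrays of a series share. No biological explanation was tested.

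In the mean of the derivatives 1514 clones passed against the parent, whereas 0 passed among the derivatives without the replicate block. That all these calls are faults of single clones is argued against by the next brightest clone. It had the same sign for 111 of 148 genes (75%, exact 95% interval 67.2% to 81.7%). Faults in a share of the calls are not excluded, since a faulty clone can also share the sign by chance. Too few arrays to see differences among derivatives fits, since 22% of simulated 4-fold differences between CPR70 and CPR20 were recovered without the replicate block. With the block 47% were recovered, so part of the low recovery comes from leaving the block out. The simulated series effect was also stronger than that of the arrays, which can lower the figure without the block. Dye bias cannot be told apart from a shared change, because the arrays with the derivative in Cy3 numbered 0. A shared change on becoming resistant stays open as an untested explanation.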

How the results depend on the processing

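The offset of 50, the filters on missing spots and blank level, the single slide series, the random effect, the calls in each series and the floor filter were chosen after the data were seen. Of 2627 values of the 119 named genes under alternatives, 2173 kept direction and side of the threshold, 437 were weaker, 0 stronger and 17 reversed. Each gene was counted only in the comparison it was first named for. The AGR2 call for CPR70 against CPR20 with the replicate block is therefore not among them. Median centring weakened 60, the series matrix log ratios 56, the random effect 38, and leave-one-out 208. Signal over background limits these ratios, since most spots of several arrays did not exceed the blank level. Both background alternatives and print-tip loess were not run, for want of background columns and layout.

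The cause was not tested for the following unless fewer clones or arrays give it. With median centring CPR20, CPR40, CPR55 and CPR70 had 2, 11, 4 and 13 clones past the threshold and the mean 397. With the series matrix log ratios they had 5, 11, 4 and 11, the mean 460, and 3 lists passed in the trend. Scaling gave about 1.0e+02 for CPR20 (65 higher, 39 lower) and 47 for CPR55. Without the dimmest 25%, CPR20 had 69; without the dimmest 50%, CPR20, CPR40 and CPR55 had 86, 144 and 233, and 5 lists passed in the trend. The replicate block gave 106, 223, 276, 391 and 2545 for the 4 derivatives and the mean, and 1 for CPR70 against CPR20. On simulated data it also gave more false calls in CPR70 and in the mean. The intensity trend with robust priors gave 82, 128 and 195 for CPR20, CPR40 and CPR55. The arrays of the derivative alone gave 216 for CPR20 and 26 for CPR55, and at least 2-fold left 451 in the mean. The offset of 50 gave 78 for CPR20, and clones measured on at least 6 arrays 54 for CPR40. Clones above the blank level on at least 4 arrays gave 112, 176, 309 and 296. The random effect left 561 in the mean, and calls in each slide series 487. The arrays of replicate 1 alone gave 7 lists in the mean and 1 in the trend, and those of replicate 2 alone 1 in the trend.

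Leave-one-out, with a lone array assumed to vary like the others, gave 0 to 43 for CPR20, 22 to 80 for CPR40, 8 to 122 for CPR55, 7 to 140 for CPR70 and 656 to 1176 for the mean. Among the derivatives, calls appeared only without CPR70 replicate 1 or without CPR40 replicate 1. In the second case CPR40 rests on replicate 2, the array with the lowest shares of gene spots above the blank level. These were 13.9% in the derivative channel and 8.9% in the parent channel, so calls made there are not read as differences. Without CPR70 replicate 1 NDRG1 read -15.05 in CPR70 against CPR20, a size that rests on 1 CPR70 array and is not read as a change. Lists past the threshold numbered 4 to 5 in the mean and 0 to 1 in the trend.

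Reversed values all belong to genes near 0 or with disagreeing clones. GCLC read -0.03 with median centring, -0.09 with the series matrix, -0.04 with clones averaged and -0.08 on replicate 2 alone. ATP7A read -0.24, -0.31 and, on replicate 1 alone, -0.08. PLAUR read -0.01 with clones averaged and ERCC1 -0.04 on replicate 1 alone, and ATP7B 0.02 on replicate 2 alone. Leave-one-out gave -0.05 to 0.13 for GCLC, -0.05 to 0.26 for ATP7A, -0.21 to 0.02 for ATP7B and -0.11 to 0.25 for ERCC1.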

Other observations

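The tests of neighbouring genes were planned before their result was seen, and the chromosome 2 stretch was chosen after it. Resistant lines can gain or lose chromosome segments, which would move neighbouring genes together. Among 6297 measured genes placed on the genome, changes in the mean of the derivatives resembled those of the next gene: the mean product of standardised changes was 0.040 over 5977 neighbouring pairs without pairs of 1 gene family, above the 95th percentile of 0.021 in 10000 shuffled orders (permutation p = 0.0013). It fell with distance, to 0.033 for genes 2 apart, 0.018 for 5 apart and 0.004 for 10 apart. At 20 and 50 apart it was 0.002 and 0.003. Families were told by the opening letters of the symbol alone. Cross-hybridisation between neighbours with like symbols is argued against as the whole cause, as the product stayed 0.019 above that percentile without such pairs. Related genes with unlike symbols stayed in, so their cross-hybridisation was not tested. Altered DNA copy number fits the planned rule and may contribute, but DNA was not measured and shared regulation of neighbouring genes was not tested. The rule used adjacent genes, which shared regulation would also move together, so it cannot tell the 2 apart. Little resemblance was left at 10 genes apart or more, so long altered segments are not shown by this test.

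The stretch of chromosome 2 from FEZ2 to PIGF had the strongest common shift among windows of 20 genes. COX7A2L lies in it and fell, while EML4, also in it, read 0.29 (adjusted p = 0.25) and so ran against the shift. In it 9 genes were lower and 0 higher. Its median was -0.46 over all arrays, -0.39 on the replicate 1 arrays and -0.62 on the replicate 2 arrays. Against the lowest of all windows in each of 1000 shuffles its permutation p was 0.044. This p covers falls alone, whereas rises were searched as well, so over both directions it would be larger.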
